A study of Rattus norvegicus with 9 samples.

How the data were processed

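RNA of hepatic macrophages from 9 male Sprague-Dawley rats was measured on biotin-labelled, 1-colour Affymetrix arrays with 36685 probesets, with 3 rats each in a sham group and in groups studied at 3 and at 10 days after PPVL (partial ligation of the portal vein). The deposited values are on the log2 scale, made by the authors with robust multi-array average (RMA) processing. The submitters' processing notes name Transcriptome Analysis Console and RMA, with versions not given in the sources used here. The deposited values had no missing entries, and no further normalization was applied. The genome build is not stated, so positions are not given. For arrays no depth applies, and the number of arrays limits the precision.

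Probesets were named from the platform's annotation. Of the 36685, 18511 carried 1 gene symbol (18166 genes), 575 carried several and 17599 carried none. For genes with several probesets, the one with the highest mean over the 9 arrays stood for the gene, which applied to 259 tested genes. Genes with a mean at or above the 30th percentile of all probesets (4.16) were tested, which left 14014. The other genes and the probesets without a single symbol were left out of the counts of genes.

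Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 9 arrays, with 6 residual and 3.59 prior degrees of freedom. The moderated test was 2-sided, without trend or robust options. Each contrast was adjusted with the Benjamini-Hochberg method, with a threshold of 0.05 and no minimum fold. A moderated F test covered the 3 groups together. With 3 rats against 3, an exact permutation test of a single gene cannot go below p = 0.1, so moderated tests were used. Whether groups overlapped was recorded per gene: in the comparison at 3 days 18.8% of the genes had no overlap between the groups, at 10 days 21.0% and between the days 14.6%, where chance gives 10%.

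Of 34 gene lists, 22 described programmes of macrophages and liver and 12 were markers of cell types. The lists of cholangiocyte and mast cell markers had 4 tested genes each, under the minimum of 5, and were not tested. Of the list genes, 76 were not found on the array and 1 was found through a synonym. Lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over the 32 lists of a contrast, and again with an estimated correlation and with fry. A list's score on an array is the mean over its genes of the log2 value minus the gene's mean over the 9 arrays.

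Genes were named by a rule. For each contrast it took the 10 largest rises and the 10 largest falls past the test with no overlap between groups. Places left over went to genes with the smallest p among those changed by at least 2-fold. From each list it took up to 4 genes, first those past the test with the largest change and then those with the smallest p. It added 13 genes whatever their values: Clec4f, Cd163, Adgre1, Cd68, Tnf, Il1b, Il6, Nos2, Arg1, Mrc1, Ccl2, Hmox1 and Alb. Unnamed loci were skipped, 1 of them at 10 days. The comparisons, tests, gene lists, this rule and the settings listed next were chosen before the data were examined.

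The procedure was tested on simulated data in 20 sets of 14014 genes for the comparison at 3 days. It found 64.5% of changes of 0.5 and 94.7% of changes of 1 (log2), and 5.24% of the calls were false. It found 20 of 20 lists shifted by 0.3, and 0.5% of 400 unshifted lists reached an unadjusted p under 0.05 with camera. Genes were simulated as independent of one another and the lists were random. These shares therefore do not cover lists of correlated genes, and the estimated correlation was 0.82 for the platelet list.

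The fits were repeated with no filter, a filter at the 50th percentile, the mean of a gene's probesets, all probesets, quantile normalization, an intensity trend with robust moderation, array weights, a replicate block, a hepatocyte score as a covariate, fits of only the 2 groups compared, other thresholds, and leaving out each array in turn. A score of the T cell and natural killer cell markers as a covariate was added after the data had been examined. Changes shared by both days were compared with 100 simulations of unchanged groups in which the sham arrays were shared. Each simulated array was a random mixture of the 6 residual dimensions, with the same weights for all genes. The 9 simulated arrays are therefore correlated with one another at random, unlike independent rats, which can widen the simulated ranges. The genes called in these simulations at each day were counted after the results had been seen. The results were also recomputed for other splits of the arrays. A list of 20 general macrophage genes, of which 19 were tested, and a list of 13 peritoneal macrophage genes, of which 10 were tested, were written after the changes had been seen. Their median differences at 3 days were 0.29 and -0.02.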

Results

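Gene expression was measured in hepatic macrophages from male Sprague-Dawley rats after partial portal vein ligation (PPVL), an operation that narrows the portal vein and is used as a model of portal hypertension. The 9 arrays fall into 3 groups of 3 rats: sham surgery, 3 days after PPVL and 10 days after PPVL. The labels describe each array as a separate rat. They give no day for the sham rats, so the time since surgery may differ between sham and either PPVL group. The days after PPVL have no sham groups of their own. Time since surgery and the course of the response to ligation therefore cannot be told apart between the days. Median signals of the arrays lay between 5.21 and 5.26 on the log2 scale. The correlation across probesets between any pair of arrays was 0.987 to 0.993. The number of arrays limits the precision. The median standard error (SE) of a log2 difference between groups was 0.0861. The series asks how the profile of hepatic macrophages changes with time after the ligation. It implies 3 comparisons, each day against sham and 10 days against 3 days. In what follows each gene's difference is a log2 difference ± its SE with n = 3 rats per group, and adjusted p is that of the moderated test of limma with Benjamini-Hochberg adjustment over 14014 genes.

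At 3 days after PPVL, the largest rise over sham past the test was that of Car4, a membrane-anchored carbonic anhydrase, by 2.18 ± 0.28 (4.53-fold, adjusted p = 0.00449). Sema3c, a secreted semaphorin, rose by 1.92 ± 0.14 (adjusted p = 0.000929), and Prg4, which encodes lubricin, rose by 1.71 ± 0.16 (adjusted p = 0.00228). Fn1, which encodes fibronectin, rose by 1.31 ± 0.10 (adjusted p = 0.000929). Csf1, the growth factor of macrophages, rose by 1.46 ± 0.24 (adjusted p = 0.0136), a call that was lost without 3-day rat 2 (adjusted p = 0.0553). Flt3, the receptor for a growth factor of dendritic cells, fell (-1.12 ± 0.18, adjusted p = 0.0116), as did Ccnd1, which encodes cyclin D1 (-1.0 ± 0.12, adjusted p = 0.00392).

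The other genes with the largest rises past the test at 3 days were Serpinb1a, an inhibitor of neutrophil proteases (2.07 ± 0.37), Fetub (1.79 ± 0.20), the membrane-bound matrix metalloproteinase Mmp14 (1.66 ± 0.19), the eosinophil-attracting chemokine Ccl24 (1.56 ± 0.24), the secreted phospholipase Pla2g2d (1.52 ± 0.23) and Wfdc15b (1.48 ± 0.25). Their adjusted p values ran from 0.00256 to 0.0186. The other genes with the largest falls past the test were Spats2l (-1.28 ± 0.17), the membrane glycoprotein gene Gpm6b (-1.21 ± 0.12), Gapt (-1.19 ± 0.20), the fatty acid elongase Elovl7 (-1.18 ± 0.21), Paqr5 (-1.16 ± 0.18), Hs3st3a1, which modifies heparan sulfate (-1.07 ± 0.11), the receptor tyrosine kinase Ephb2 (-1.06 ± 0.16) and Slc46a3 (-1.0 ± 0.17). Their adjusted p values ran from 0.00228 to 0.0186. Leaving out 1 array ended the calls of Serpinb1a (adjusted p up to 0.0706), Wfdc15b (0.0506), Gapt (0.0654), Elovl7 (0.0690) and Slc46a3 (0.0659) in at least 1 fit.

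In all, 401 of 14014 genes changed at 3 days, 301 up and 100 down, and 52 of them by 2-fold or more (44 up and 8 down). At an unadjusted p under 0.05 there were 2171 genes, where 700.7 are expected by chance. In 100 simulations of unchanged groups against shared sham arrays, 3 gave 401 genes or more, up to 1158, and 96 gave none. The simulated arrays were correlated with one another at random, unlike independent rats, so these counts are a rough guide. Of the 63 genes named at 3 days that passed the test, 34 passed in each of the 9 fits that left out 1 array. The count was 190 to 327 in these fits, and it was 256 without sham rat 1, 190 without sham rat 2, 240 without sham rat 3 and 194 without 3-day rat 2. It was 0 with a T and natural killer cell marker score as a covariate, a score that itself differed between the groups (958 genes at an unadjusted p under 0.05 with limma). It was 191 with all probesets, 134 with only the 2 groups compared in the fit and 260 with a hepatocyte score as a covariate. Of the 401 genes, 128 were among the 134 and 203 among the 260. Still called were 210 of the 401 without sham rat 1, 181 without sham rat 2 and 220 without sham rat 3. Without 3-day rat 2 these were 164.

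**Figure D1:**
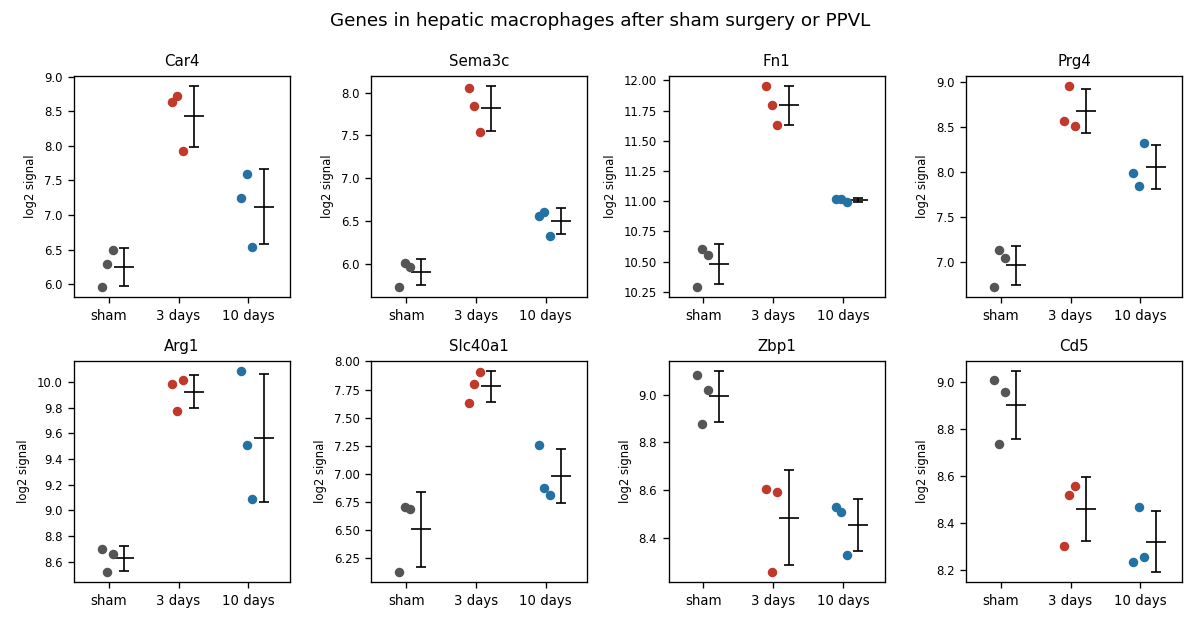
Log2 signal of 8 genes on each array (y axis) in the sham, 3-day and 10-day groups (x axis). Points are single rats, and the bar beside them is the mean with its SD (n = 3). Sema3c and Fn1 lie highest at 3 days, by 1.92 and 1.31 over sham, and the T cell gene Cd5 differs by -0.58 from sham at 10 days.

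Among the gene lists fixed beforehand, that of recruited monocytes had the smallest p at 3 days. Of its 14 tested genes, 7 rose over all genes tested and 10 rose when adjusted over the list alone. They include Fn1, the proteoglycan Vcan (1.24), the integrin Itgam, known as CD11b (0.89), and the chemokine receptor Ccr2 (0.85). As a set the list was higher with camera, limma's test of a list against all other genes (adjusted p = 9.53e-12, and adjusted p = 0.0794 with an estimated correlation). In the scar-associated macrophage list, 6 of 13 genes rose, 10 adjusted over the list alone, among them galectin-3 (Lgals3, 0.94), cathepsin L (Ctsl, 0.91), osteopontin (Spp1, 0.91) and Gpnmb (0.86). Its shift had adjusted p = 2.87e-09, and adjusted p = 0.0794 with an estimated correlation. In the matrix remodelling list, 5 of 19 genes rose, 12 adjusted over the list alone, where 1 fell. Besides Mmp14 and Fn1 these were led by Tgfbi (0.78) and the plasminogen activator Plau (0.64) (adjusted p = 2.60e-07, and adjusted p = 0.192 with an estimated correlation). In the alternative activation list, 5 of 18 genes rose, 11 adjusted over the list alone, where 1 fell. Besides Ccl24 these include arginase 1 (Arg1, 1.30), Egr2 (0.66) and Chi3l1 (0.51) (adjusted p = 7.17e-06, and adjusted p = 0.0794 with an estimated correlation). Leaving out 1 array ended the calls of Ccr2 (adjusted p up to 0.110), Spp1 (0.0714), Plau (0.114) and Chi3l1 (0.141) in at least 2 fits, and that of Chi3l1 in all 9. On the same arrays the T cell marker score differed from sham by -0.28 and the natural killer cell marker score by -0.23, and the latter by -0.081 without 3-day rat 3.

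Vessel-related and iron-related genes were also among those that rose. In the list of vasoactive mediators, Arg1, thromboxane synthase (Tbxas1, 1.06) and Ddah1, which breaks down an inhibitor of nitric oxide synthesis (0.55), rose, 3 of 19 genes and 7 adjusted over the list alone (adjusted p = 6.76e-05, and adjusted p = 0.0794 with an estimated correlation). In the iron and haem list 2 of 18 genes rose, 4 adjusted over the list alone: the iron exporter ferroportin (Slc40a1, 1.27) and Lrp1 (0.85) (adjusted p = 1.28e-05, and adjusted p = 0.119 with an estimated correlation). Slc40a1 and the ficolin Fcna (0.75) were the 2 of 13 Kupffer cell identity genes that rose, 3 adjusted over the list alone (adjusted p = 0.000898, and adjusted p = 0.119 with an estimated correlation). Clec4f, a lectin of Kupffer cells, and the haemoglobin scavenger receptor Cd163 did not pass the test, with differences of 0.55 ± 0.23 and 0.31 ± 0.19, and their mean signals of 5.03 and 4.50 lay close to the filter for dim genes at 4.16. Without 3-day rat 3 these differences were 0.24 and 0.082, and that of Cd163 was 0.53 without 3-day rat 2. Of 20 phagocytic and scavenger receptors, Clec4a1 (1.01), Msr1 (0.93) and Lrp1 rose and Mfge8 fell (-0.39). Adjusted over the list alone, 7 rose and 1 fell (adjusted p = 0.000469, and adjusted p = 0.216 with an estimated correlation). Neu1 (0.56) and Ctsd (0.49) rose among 18 lysosome genes, 3 adjusted over the list alone (adjusted p = 5.09e-05, and adjusted p = 0.192 with an estimated correlation). Fabp4 (1.12) was the single riser of 18 lipid handling genes, with 4 adjusted over the list alone (adjusted p = 0.00248, and adjusted p = 0.203 with an estimated correlation). The calls of Clec4a1 (adjusted p up to 0.0547), Mfge8 (0.102), Neu1 (0.130) and Ctsd (0.133) were lost in at least 1 fit without 1 array.

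Genes of inflammatory signalling were also among those that rose at 3 days. The endotoxin co-receptor Cd14 rose (0.92), as the only one of 19 Toll-like receptor genes, with 2 up and 1 down adjusted over the list alone (adjusted p = 0.00240, and adjusted p = 0.216 with an estimated correlation). Nlrp3 (0.65) and Cd40 (0.47) rose among 21 inflammatory genes, with 3 up and 2 down adjusted over the list alone (adjusted p = 0.0220, and adjusted p = 0.396 with an estimated correlation). That shift was not called without sham rat 1 (adjusted p = 0.107) or 3-day rat 2 (adjusted p = 0.255). Tnf (0.34 ± 0.17), Il1b (0.36 ± 0.12), Il6 (0.15 ± 0.28), Nos2 (0.10 ± 0.10), Ccl2 (0.32 ± 0.08), Hmox1 (0.46 ± 0.12), Mrc1 (0.73 ± 0.22), Cd68 (0.39 ± 0.13) and Adgre1 (0.18 ± 0.12) did not pass the test. The differences of Adgre1 (0.089 to 0.30 without 1 array), Tnf (0.21 without sham rat 1), Il6 (-0.20 to 0.45) and Nos2 (0.039 to 0.15) moved by over 1.5 times when 1 array was left out. Of 20 chemokines Ccl24 rose, and 5 rose adjusted over the list alone (adjusted p = 0.0426, and adjusted p = 0.437 with an estimated correlation). The chemokine shift was not called in 5 of the 9 fits without 1 array, those without sham rat 1, 2 or 3, 3-day rat 2 or 10-day rat 2, with adjusted p up to 0.485. RT1-DOa rose (0.53) among 12 class II presentation genes, with 3 adjusted over the list alone (adjusted p = 0.0145, and adjusted p = 0.388 with an estimated correlation), and the shift was not called without sham rat 1 (adjusted p = 0.107) or 3-day rat 3 (adjusted p = 0.0887). In fits without 1 array the calls of Cd14 (adjusted p up to 0.0783), Nlrp3 (0.120), Cd40 (0.113) and RT1-DOa (0.112) were lost at least 4 times.

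Type I interferon response genes were lower at 3 days. Zbp1 (-0.51), Ifih1 (-0.51) and Rig1 (-0.37), which sense nucleic acids, fell among 28 genes. Adjusted over the list alone, 16 fell and 1 rose (adjusted p = 3.44e-11, and adjusted p = 0.216 with an estimated correlation). The median difference of the list was -0.48. The 3 single genes kept their calls in 2 (Zbp1), 1 (Ifih1) and 1 (Rig1) of 9 fits without 1 array, with adjusted p up to 0.120, 0.154 and 0.137.

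Markers of other cell types moved with the same comparison. None of 16 T cell genes passed over all genes, and 9 fell adjusted over the list alone, among them Cd5 (-0.44) and Lck (-0.41) (adjusted p = 7.17e-06, and adjusted p = 0.216 with an estimated correlation). None of 12 natural killer cell genes fell, over all genes or adjusted over the list alone, and their median difference was -0.23 (adjusted p = 0.00134, and adjusted p = 0.391 with an estimated correlation). The natural killer cell shift was not called without 3-day rat 3 (adjusted p = 0.179), where the score differed by -0.081 and not by -0.23. B cell genes were higher, with Vpreb3 (0.83) and Cr2 (0.75) risen of 13 genes, and 5 adjusted over the list alone (adjusted p = 7.17e-06, and adjusted p = 0.267 with an estimated correlation). The B cell score was 0.41 in 3-day rat 3 and -0.01 and -0.16 in rats 1 and 2, so that the difference of 0.38 from sham was 0.22 without rat 3. Platelet genes had a median difference of 0.54, with none of 6 genes passing, also when adjusted over the list alone (adjusted p = 0.0145, and adjusted p = 0.408 with an estimated correlation). Their score was 0.62 and 0.71 in 3-day rats 1 and 3 and -0.18 in rat 2, and the shift was not called without sham rat 2 (adjusted p = 0.0698), 3-day rat 1 (adjusted p = 0.101) or 3-day rat 3 (adjusted p = 0.0979). The platelet score difference of 0.46 from sham was 0.74 without rat 2 and 0.29 without rat 3. Of 12 hepatocyte genes the haptoglobin gene Hp rose (0.72), also adjusted over the list alone (adjusted p = 0.0206, and adjusted p = 0.285 with an estimated correlation), and the shift was not called without sham rat 2 or 3-day rat 1 or 3, with adjusted p up to 0.116. The single-gene calls of Vpreb3 (adjusted p up to 0.101), Cr2 (0.0704) and Hp (0.0697) were lost in at least 3 fits without 1 array. Albumin (Alb) differed by 0.75 ± 0.39, which did not pass, and by 0.33 without 3-day rat 3, 1.19 without 3-day rat 2 and 0.44 without sham rat 2.

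Some single genes passed in lists that did not. The dendritic cell genes Flt3, Clec9a (-0.67) and Irf8 (-0.38) fell, of 9 tested, and adjusted over the list alone 2 rose and 3 fell (adjusted p = 0.102 for the list). The granulocyte genes Fcnb (1.23) and Csf3r (1.04) rose, of 14 neutrophil genes, over all genes and adjusted over the list alone (adjusted p = 0.0828 for the list). The neutrophil score was -0.75 in sham rat 1 and 0.19 in each of the other sham rats. Angpt1 (0.79) and Nrp2 (0.56) rose among 16 angiogenic genes (adjusted p = 0.298 for the list), and Ldha fell (-0.30) among 20 hypoxia and glycolysis genes (adjusted p = 0.433). Ecm1 rose (0.60) among 12 stellate cell genes (adjusted p = 0.281) and Kit fell (-0.55), a mast cell marker whose list had 4 tested genes and was not tested. Leaving out 1 array ended the calls of Clec9a (adjusted p up to 0.0636), Csf3r (0.0978), Ldha (0.109), Ecm1 (0.130) and Kit (0.153) in at least 2 fits. The remaining lists were those of cell cycle, cholesterol synthesis, oxidative phosphorylation, endoplasmic reticulum stress, dissociation stress, sinusoidal endothelial and erythroid genes, with adjusted p between 0.247 and 0.976. In the endoplasmic reticulum stress, dissociation stress and sinusoidal endothelial lists the median and the mean difference had opposite signs. Of the 32 lists tested, 20 passed with the preset correlation of 0.01, 17 up and 3 down, and 12 passed with fry. None passed with an estimated correlation, where 8 of the 20 had an unadjusted p under 0.05. With the T and natural killer cell score as a covariate 7 passed, and the class II, B cell and natural killer cell lists turned direction.

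**Figure D2:**
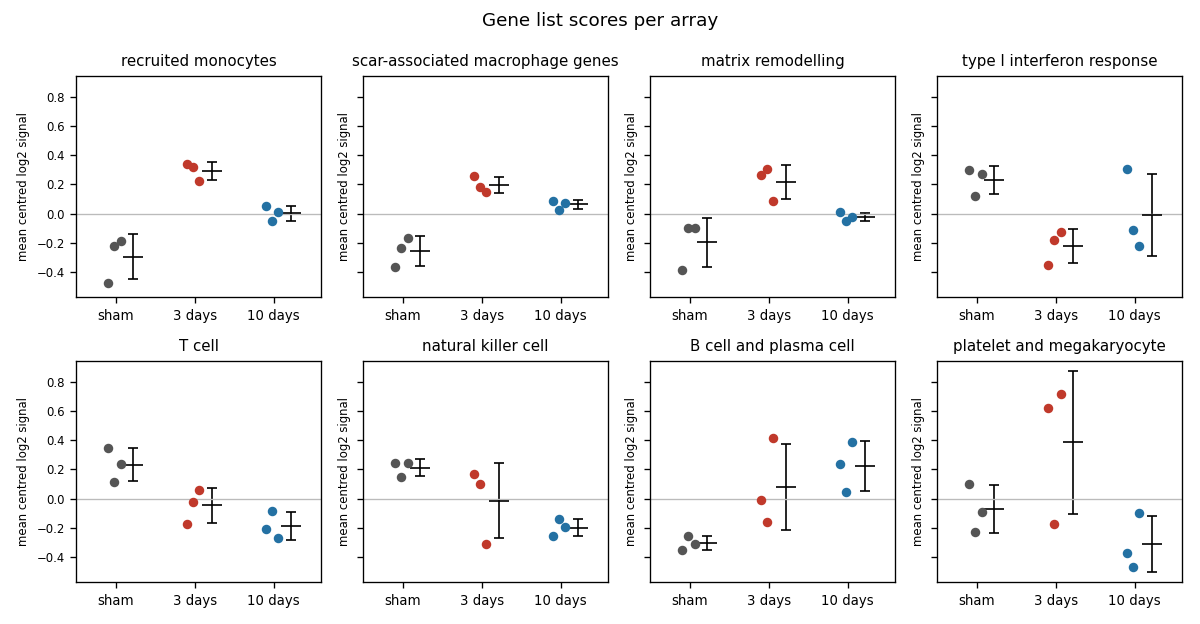
Score of 8 gene lists on each array (y axis, mean over the list of each gene's log2 signal minus its mean over the 9 arrays) in the sham, 3-day and 10-day groups (x axis). Points are single rats, and the bar beside them is the mean with its SD (n = 3). The recruited monocyte score is -0.30 in sham, 0.29 at 3 days and 0.00 at 10 days, and the T cell score is 0.23, -0.05 and -0.19.

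At 10 days after PPVL the largest rises over sham past the test were those of Pla2g2d, by 1.29 ± 0.23 (adjusted p = 0.0485), Prg4, by 1.09 ± 0.16 (adjusted p = 0.0438), and Fam20c, a kinase of secreted proteins, by 1.08 ± 0.18 (adjusted p = 0.0449). Genes of lymphocytes were among those that fell, with the granzyme Gzmc at -0.70 ± 0.13 (adjusted p = 0.0491) and the T cell surface gene Cd5 at -0.58 ± 0.10 (adjusted p = 0.0449). The lysophosphatidic acid receptor Lpar5 fell by 0.96 ± 0.11 and the metallothionein Mt2A fell by 0.86 ± 0.15 (adjusted p = 0.0400 and 0.0485). The co-stimulatory ligand Cd80 rose by 0.82 ± 0.14 (adjusted p = 0.0449). Each of these calls was lost in several fits without 1 array, with adjusted p up to 0.169 for Gzmc and 0.143 for Lpar5.

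Further rises past the test at 10 days were those of the pyrophosphatase Enpp1 (0.90 ± 0.15), B4galt6 (0.90 ± 0.14), Myof (0.87 ± 0.13), Arhgap22 (0.87 ± 0.13), the extracellular sulfatase Sulf2 (0.84 ± 0.11) and the paraoxonase Pon3 (0.84 ± 0.15). Further falls past the test were those of Hs3st3b1 (-0.82 ± 0.10), Gfra3 (-0.81 ± 0.11), Gpm6b (-0.73 ± 0.12), Dmtn (-0.67 ± 0.11), the lymphocyte adaptor Sla2 (-0.65 ± 0.11), Pacs2 (-0.64 ± 0.11) and Slc12a7 (-0.64 ± 0.11). Their adjusted p values ran from 0.0400 to 0.0485. Without 1 array each call was lost in at least 5 of 9 fits, with adjusted p up to 0.169.

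In all, 103 genes changed at 10 days, 69 up and 34 down, 3 of them by 2-fold or more. At an unadjusted p under 0.05 there were 2271 genes. In the 100 simulations of unchanged groups, 1 gave 103 genes or more, with 249, and 97 gave none. The calls lay just under the threshold: the count was 0 with no filter on dim genes, with all probesets or with the T and natural killer cell score as a covariate (606 genes at an unadjusted p under 0.05 with limma in the last), and it was 0 without sham rat 2, sham rat 3 or 10-day rat 3, 1 without 10-day rat 1, 2 without 10-day rat 2, 11 without sham rat 1 and 45 without 3-day rat 2. It was 61 with only the 2 groups compared in the fit and 31 with the hepatocyte score, and 170 to 197 with quantile normalization, a stricter filter, an intensity trend or array weights. Some of the genes in these fits were not among the 103. Of the 11 without sham rat 1, 3 were, and of the 45 without 3-day rat 2, 37 were. With only the 2 groups compared 40 of the 61 were, and with the hepatocyte score 18 of the 31. Of the 33 genes named at 10 days that passed, none passed in all 9 fits that left out 1 array.

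Lists of macrophage genes were also higher than sham at 10 days, on arrays whose T cell marker score differed from sham by -0.42 and natural killer cell marker score by -0.41. Gpnmb (0.75), Ctsl (0.67) and Lgals3 (0.55) rose, 3 of 13 scar-associated macrophage genes, with 8 adjusted over the list alone (adjusted p = 7.41e-07, and adjusted p = 0.286 with an estimated correlation). Itgam rose (0.78), as 1 of 14 recruited monocyte genes, with 5 adjusted over the list alone (adjusted p = 0.000120, and adjusted p = 0.323 with an estimated correlation). Lrp1 (0.73) and Msr1 (0.52) rose and Mfge8 fell (-0.54) among 20 phagocytic receptors, with 8 up and 2 down adjusted over the list alone (adjusted p = 0.0144, and adjusted p = 0.366 with an estimated correlation). Lrp1 was also the 1 gene that rose of 18 iron and haem genes, likewise 1 adjusted over the list alone (adjusted p = 0.0275, and adjusted p = 0.365 with an estimated correlation). Tbxas1 rose (0.81) among 19 vasoactive genes, with 5 up and 1 down adjusted over the list alone (adjusted p = 0.0194, and adjusted p = 0.286 with an estimated correlation). Egr2 rose (0.61) among 18 alternative activation genes, with 7 up and 3 down adjusted over the list alone (adjusted p = 0.0194, and adjusted p = 0.323 with an estimated correlation), and Arg1 differed by 0.94 ± 0.20, which did not pass. No gene passed in the lists of matrix remodelling, with 7 up and 1 down adjusted over the list alone (adjusted p = 0.00435, and adjusted p = 0.388 with an estimated correlation), and lysosome genes, with 3 up adjusted over the list alone (adjusted p = 0.00790, and adjusted p = 0.365 with an estimated correlation). Without sham rat 1 the shifts of alternative activation, phagocytic receptor, iron, matrix and lysosome genes were not called, with adjusted p = 0.0687, 0.0699, 0.123, 0.0699 and 0.0687. The iron shift was also not called without 10-day rat 1 or 2 (adjusted p = 0.0779 and 0.0612), nor the vasoactive shift without 10-day rat 2 (adjusted p = 0.0612). The single-gene calls were each lost in at least 5 of 9 fits without 1 array, with adjusted p up to 0.169.

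Lymphocyte markers moved in both directions at 10 days. Cd5 fell over all genes, and 15 of 16 T cell genes fell adjusted over the list alone (adjusted p = 2.79e-11, and adjusted p = 0.286 with an estimated correlation). No natural killer cell gene passed over all genes, and 9 of 12 fell adjusted over the list alone, among them perforin (Prf1, -0.51) and Gzmb (-0.78) (adjusted p = 9.19e-08, and adjusted p = 0.323 with an estimated correlation). No B cell gene passed over all genes, and 10 of 13 rose adjusted over the list alone, among them Ms4a1, which encodes CD20 (0.77), and Bank1 (0.63) (adjusted p = 1.04e-08, and adjusted p = 0.323 with an estimated correlation). RT1-DOa rose (0.58) among 12 class II presentation genes, with 4 adjusted over the list alone (adjusted p = 0.000503, and adjusted p = 0.323 with an estimated correlation). Type I interferon genes were lower as a list, with none passing and 2 of 28 fallen adjusted over the list alone (adjusted p = 0.000136, and adjusted p = 0.435 with an estimated correlation). Their score was 0.30, -0.11 and -0.22 in 10-day rats 1, 2 and 3, and the shift was not called without rat 3 (adjusted p = 0.0547). The calls of Cd5 and RT1-DOa were kept in 2 of 9 fits without 1 array, with adjusted p up to 0.159 and 0.160. With the T and natural killer cell score as a covariate RT1-DOa differed by -0.046.

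The other 19 lists did not pass at 10 days, with adjusted p between 0.0546 for hepatocyte genes and 0.726 for neutrophil genes. In the inflammatory and neutrophil lists the median and the mean difference had opposite signs. Fcna of the Kupffer cell list (0.52), Cd80 of the inflammatory list and Nrp2 of the angiogenic list (0.54) rose, calls lost in at least 6 of 9 fits without 1 array (adjusted p up to 0.153). Among the genes fixed beforehand, Clec4f (0.62 ± 0.23), Cd163 (0.14 ± 0.19), Adgre1 (0.50 ± 0.12), Cd68 (0.27 ± 0.13), Tnf (0.04 ± 0.17), Il1b (-0.02 ± 0.12), Il6 (-0.61 ± 0.28), Nos2 (-0.06 ± 0.10), Mrc1 (0.19 ± 0.22), Ccl2 (0.14 ± 0.08), Hmox1 (0.35 ± 0.12) and Alb (0.67 ± 0.39) did not pass. Without 1 array 9 of the 13 fixed genes moved by over 1.5 times at 10 days, among them Alb (0.36 without sham rat 2), Mrc1 (0.033 to 0.40) and Cd163 (0.040 to 0.22), and Tnf, Il1b and Nos2 changed sign. Of the 32 lists tested, 13 passed with the preset correlation, 10 up and 3 down. With fry 3 passed, and with an estimated correlation none, where 3 of the 13 had an unadjusted p under 0.05. With the T and natural killer cell score as a covariate none passed with camera (3 of the 32 had an unadjusted p under 0.05), and 7 of the 13 turned direction: class II, B cell, T cell, natural killer cell, phagocytic receptor, iron and lysosome genes.

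**Figure D3:**
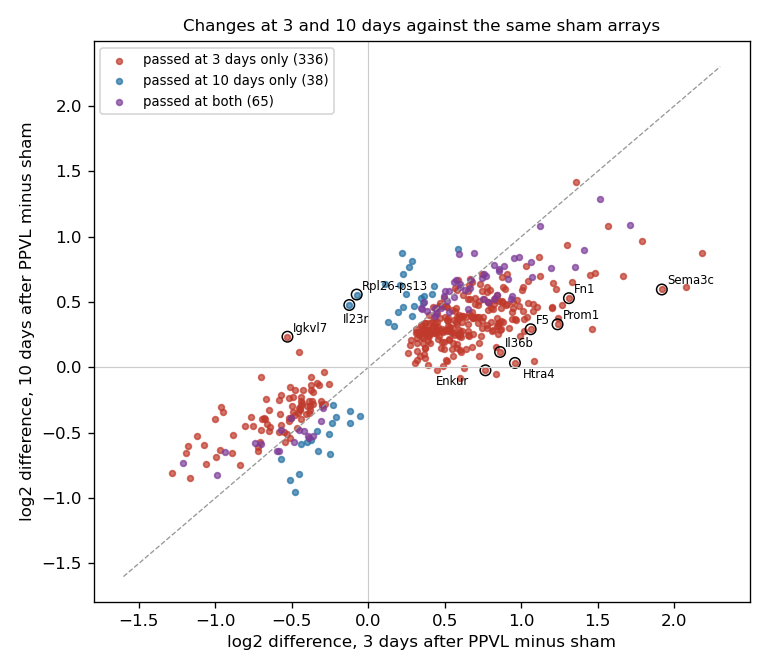
Log2 difference from sham at 3 days (x axis) and at 10 days (y axis) for the 439 genes that passed in at least 1 of the 3 comparisons (points, coloured by the comparison with sham that they passed). The dashed line marks equal differences, and circled names are the 10 genes that changed between 3 and 10 days, such as Sema3c at 1.92 and 0.60.

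Between 3 and 10 days after PPVL, 7 genes fell and 3 rose. Sema3c fell by 1.32 ± 0.14 (adjusted p = 0.0165), Fn1 fell by 0.78 ± 0.10 (adjusted p = 0.0324) and F5, which encodes coagulation factor V, fell by 0.77 ± 0.08 (adjusted p = 0.0165). The serine protease gene Htra4 (-0.92 ± 0.10, adjusted p = 0.0194), Prom1, which encodes CD133 (-0.91 ± 0.11, adjusted p = 0.0291), Enkur (-0.79 ± 0.08, adjusted p = 0.0165) and the cytokine gene Il36b (-0.74 ± 0.10, adjusted p = 0.0324) also fell. The immunoglobulin light chain gene Igkvl7 (0.76 ± 0.09, adjusted p = 0.0324), Rpl26-ps13 (0.63 ± 0.09, adjusted p = 0.0461) and the cytokine receptor gene Il23r (0.60 ± 0.08, adjusted p = 0.0324) rose. Il23r had a mean signal of 3.96 at 3 days, below the filter at 4.16. Serpinb10 (-1.27 ± 0.22), Mirlet7f-1os (-1.27 ± 0.20), Ccin (-1.06 ± 0.21) and RT1-T24-3 (1.21 ± 0.26) differed by at least 2-fold and did not pass, with adjusted p from 0.111 to 0.197. At an unadjusted p under 0.05 there were 1578 genes. None of the 10 genes passed in all 9 fits that left out 1 array, and 2 of them passed in none of these fits. The count was 0 without sham rat 2, 3-day rat 1 or 10-day rat 3. It was 1 without 10-day rat 1, 4 without sham rat 3, 5 without 10-day rat 2 and 18 without 3-day rat 2. It was also 0 with all probesets and with the T and natural killer cell score as a covariate (987 genes at an unadjusted p under 0.05 with limma in the latter), 3 with only the 2 groups compared in the fit and 20 with the hepatocyte score. Of the 18 genes called without 3-day rat 2, 5 were among the 10. Of the 20 called with the hepatocyte score 9 were, and of the 3 called with only the 2 groups compared 1 was. Without 1 array the adjusted p reached 0.127 for Sema3c, 0.187 for Fn1 and 0.189 for Rpl26-ps13.

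Lists of monocyte and macrophage genes were lower at 10 than at 3 days. Of 14 recruited monocyte genes Fn1 fell, and 5 fell adjusted over the list alone (adjusted p = 6.49e-05, and adjusted p = 0.272 with an estimated correlation), among them Vcan (-0.86). Fn1 was also the 1 gene that fell of 19 matrix remodelling genes, with 4 adjusted over the list alone (adjusted p = 0.00107, and adjusted p = 0.469 with an estimated correlation), where Mmp14 differed by -0.97 ± 0.19 and Timp1 by -0.73 ± 0.15. No gene passed over all genes in the other 12 lists that moved. Platelet genes had a median difference of -0.67, and 5 of 6 fell adjusted over the list alone, among them Pf4 (-1.38) (adjusted p = 6.49e-05, and adjusted p = 0.370 with an estimated correlation). Immediate early genes were lower, with none fallen adjusted over the list alone (adjusted p = 0.000351, and adjusted p = 0.272 with an estimated correlation), and T cell genes were lower again, with 1 of 16 adjusted over the list alone (adjusted p = 0.00543, and adjusted p = 0.502 with an estimated correlation). Natural killer cell (adjusted p = 0.00461, and adjusted p = 0.502 with an estimated correlation) and alternative activation genes (adjusted p = 0.00543, and adjusted p = 0.272 with an estimated correlation) were lower, with none fallen adjusted over the list alone. Kupffer cell identity (adjusted p = 0.0102, and adjusted p = 0.272 with an estimated correlation), iron and haem (adjusted p = 0.0153, and adjusted p = 0.419 with an estimated correlation) and scar-associated macrophage genes (adjusted p = 0.0279, and adjusted p = 0.489 with an estimated correlation) were lower, with 1 gene each fallen adjusted over the list alone.

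Vasoactive genes were lower too, with 3 fallen adjusted over the list alone (adjusted p = 0.0412, and adjusted p = 0.272 with an estimated correlation). Type I interferon genes were higher at 10 than at 3 days, with none risen adjusted over the list alone (adjusted p = 0.000351, and adjusted p = 0.542 with an estimated correlation), and the shift was not called without 10-day rat 1 (adjusted p = 0.232). Cholesterol synthesis genes were higher, with 1 risen adjusted over the list alone, and this was Sqle, an enzyme of the pathway (0.65) (adjusted p = 0.0210, and adjusted p = 0.502 with an estimated correlation). Dendritic cell genes were higher, with 2 risen adjusted over the list alone (adjusted p = 0.0349, and adjusted p = 0.272 with an estimated correlation). Of the 14 lists that passed, 3 up and 11 down, those of recruited monocytes, matrix remodelling, immediate early and platelet genes passed in all 9 fits that left out 1 array. The lists of T cell, natural killer cell, Kupffer cell, alternative activation, iron, vasoactive, scar-associated, cholesterol and dendritic cell genes lost their call without 1 or more of the 3-day or 10-day rats, with adjusted p up to 0.268, and the vasoactive list also without sham rat 3. None of the 14 passed with fry or with an estimated correlation, where 5 had an unadjusted p under 0.05. With the T and natural killer cell score as a covariate 11 lists passed, and the T cell and natural killer cell lists turned direction.

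Both days were compared with the same 3 sham rats, so their changes share the chance values of those arrays. Of the 401 and 103 changed genes, 65 changed at both days, 48 up and 17 down, and none in opposite directions. Among the genes up at both days were Pla2g2d, Prg4, Itgam, Lrp1, Tbxas1 and Gpnmb, and among those down at both were Gpm6b and Mfge8. Independent lists of these sizes would share 1.48 up and 0.243 down. In 100 simulations of unchanged groups against shared sham arrays, 98 shared no gene and 1 shared as many as 65. The log2 differences at both days had a covariance of 0.0248, where the simulations had a mean of 0.00660 and ranged from -0.00585 to 0.0347, and a correlation across genes of 0.654, where the simulations had a mean of 0.470 and ranged from -0.786 to 0.929. The 3 shared controls add to both measures and are too few to be split. Over all genes tested, 69.0% had the same sign at both days, where the simulations had a mean of 66.8% and ranged from 21.4 to 87.5%. Random correlation among the simulated arrays can widen these ranges. The overlap was 0 without sham rat 2, sham rat 3, 10-day rat 1 or 10-day rat 3 and with no filter on dim genes, 1 without 10-day rat 2, 9 without sham rat 1 and 26 without 3-day rat 2. A moderated F test found 329 genes that differed among the 3 groups, of which 271 had changed at 3 days and 102 at 10 days. Without 1 array the F test count was 156, 54 and 90 (sham rats 1, 2 and 3), 196 (3-day rat 2) and 126, 202 and 127 (10-day rats 1, 2 and 3).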

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

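The tests of general macrophage genes, of B cell markers, of the spread among the 10-day arrays and the T and natural killer cell score as a covariate were chosen after the result was seen, and the limits of the general macrophage test for the smaller rises were narrowed once its values were known.

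A first pattern is that genes were higher after PPVL while T cell and natural killer cell markers were lower. A larger share of macrophage RNA would raise general macrophage genes. At 3 days 19 of them, 6 being members of the fixed lists, had a median of 0.29 (SD over genes 0.28, range -0.25 to 0.92). The 44 genes that rose 2-fold or more had a median of 1.21. They were picked by the size of their rise, so a higher median was fixed beforehand. This comparison cannot decide whether a larger share is the whole cause of those rises. For the 257 genes that rose by less (median 0.59) a larger share and a change within macrophages cannot be told apart either. A gene with the median SE needs a change of about 0.38 to reach the test, so the selection favoured larger changes. A lower share of all lymphocytes alike is argued against by the B cell score, which was 0.53 higher at 10 days than in sham (pooled SD between arrays 0.20). A mixture of cell types that follows the groups stays open, because the T and natural killer cell score was 0.13 to 0.30 in sham rats and 0.030 or lower in all others, so that a fit with it cannot separate it from the groups: no gene passed limma's test in any contrast (958 genes at an unadjusted p under 0.05 at 3 days, 606 at 10 days and 987 between the days), as errors grew and, at 10 days, changes shrank, where the median change of the 401 genes went from 0.60 to 0.55 and their median SE from 0.104 to 0.205, for the 103 genes from 0.57 to 0.39 and from 0.0961 to 0.269, and for the 10 genes from 0.78 to 0.74 and from 0.0955 to 0.132.

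A second pattern is that fewer genes changed at 10 than at 3 days by the adjusted test (103 and 401). At an unadjusted p under 0.05 the order was the opposite (2271 and 2171 genes), as it was for genes with no overlap between the groups (21.0% and 18.8%, where chance gives 10%), while an adjusted p under 0.10 (444 and 709) and an unadjusted p under 0.05 with 2-fold (10 and 63) kept it, so the pattern depends on the threshold. The ratio of the median SD of the 10-day arrays to that of the 3-day arrays was 1.02. The main fit pooled the variance of a gene over all groups, so its SE was the same at both days. A larger spread among the 10-day arrays would raise both SEs alike. The ratio therefore cannot decide whether spread lowered the 10-day count. Selection of the genes by their 3-day values may account for smaller 10-day changes of the 401 genes (median 0.60 and 0.38, 364 of them smaller at 10 days). Most of the 103 genes called at 10 days had the smaller change at 3 days, and 41 had the larger one there. Their median difference was -0.062 (pooled SD of the score 0.0570), and the arrays overlapped (0.12, 0.22 and 0.16 at 3 days, 0.27, 0.15 and 0.24 at 10 days). The size of the selection effect cannot be read from this difference, because a weakening with time would reduce it. A weakening of the response with time stays open as a biological explanation, and it was tested for single genes only by the difference between the days.

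Other splits of the arrays were counted for each result. For 3 rats against 3 there are 10 splits, too few for a share under 0.05. At 3 days the real split gave 401 genes and the highest other 0, with 1 of 10 splits as large, and for lists 20 and 20, with 2 of 10. At 10 days these were 103 genes and 0 (1 of 10) and 13 lists and 12 (1 of 10). Between the days they were 10 genes and 1 (1 of 10) and 14 lists and 10 (1 of 10). For the F test, 1 of 100 splits drawn from 280 gave as many genes, the real one with 329 against 42 at most. For the shared changes it was also 1 of 100, with 65 against 14 at most. A share of 1 of 100 is the lowest these splits can give. For the F test they argue against chance and do not exclude it. The simulations of unchanged groups were not counted for the F test. For the shared changes the splits cannot decide, because a split with few called genes has few to share. In 92 of the other splits the F test called no gene, and these splits shared none. The split with 14 shared genes kept the 3 sham rats together. Among the simulations of unchanged groups with shared sham arrays, 1 of 100 shared as many genes, and the correlation of 0.654 lay within their range.

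The effects at 3 and 10 days differed by limma's test of the difference for 10 genes. They were Sema3c (-1.32, adjusted p = 0.0165), Htra4 (-0.92, adjusted p = 0.0194), Prom1 (-0.91, adjusted p = 0.0291), Enkur (-0.79, adjusted p = 0.0165), Fn1 (-0.78, adjusted p = 0.0324), F5 (-0.77, adjusted p = 0.0165), Il36b (-0.74, adjusted p = 0.0324), Igkvl7 (0.76, adjusted p = 0.0324), Rpl26-ps13 (0.63, adjusted p = 0.0461) and Il23r (0.60, adjusted p = 0.0324). Igkvl7 differed from sham by -0.53 at 3 days and 0.23 at 10 days. None was called in all 9 fits without 1 array, and 2 were called in none of them. The counts were 0 without sham rat 2, 3-day rat 1 or 10-day rat 3.

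For 14 lists the effects at the 2 days differed by camera with the preset correlation, and for none with an estimated correlation, where adjusted p ran from 0.272 to 0.542. The median differences between the days were -0.21 for recruited monocytes, -0.67 for platelet, -0.12 for immediate early, -0.16 for matrix remodelling, -0.18 for natural killer cell, -0.12 for alternative activation, -0.12 for T cell, -0.17 for Kupffer cell, -0.11 for iron, -0.092 for scar-associated macrophage and -0.11 for vasoactive genes. They were 0.19 for type I interferon, 0.10 for cholesterol synthesis and 0.086 for dendritic cell genes. Leaving out 1 array moved the difference in mean score by over 1.5 times for type I interferon genes (0.21, 0.051 without 10-day rat 1 and 0.31 without 10-day rat 3), Kupffer cell genes (-0.20, -0.092 without 3-day rat 3), natural killer cell genes (-0.18, -0.093 without 3-day rat 1 and -0.33 without 3-day rat 3) and T cell genes (-0.14, -0.088 without 3-day rat 3).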

How the results depend on the processing

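The T and natural killer cell score as a covariate was chosen after the result was seen, and the other alternatives were planned.

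The 3-day count was within 1.5 times of 401 with no filter, the 50th percentile filter, probeset means, quantile normalization, the intensity trend and array weights (324 to 530). Direction could change with probeset means, quantile normalization, array weights, the covariates and 1 array left out of the groups compared. The 401, 103 and 10 called genes kept theirs in these fits, except that 100 of the 103 did with the T and natural killer cell score. Of the alternative values of named genes 8455 kept their side of the threshold, 813 lost and 116 gained a call, and 1 turned. For lists these were 1504, 156, 49 and 13. Values that failed the test both in the main fit and in the alternative count as kept. The tallies therefore do not give the share of calls that held. At 10 days without sham rat 2, all 33 calls of named genes were lost, while 127 values counted as kept. Signals below or close to the filter on dim genes limit some results, such as those of Il23r, Clec4f and Cd163.

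With no filter the 10-day count was 0 (2271 genes at an unadjusted p under 0.05 with the filter) and the overlap 0, and more genes enter the adjustment. With the 50th percentile filter it was 173, with fewer genes tested. With all probesets, where 25679 were tested, the counts were 191 at 3 days, 0 at 10 days, 0 between the days and 81 for the F test. Quantile normalization gave 170 at 10 days and an overlap of 106, and between the days 8 genes, 1 up and 7 down. The intensity trend gave 173 and array weights 197 at 10 days, and the cause was not tested. The hepatocyte score gave 260 at 3 days, 31 at 10 days, 20 between the days and 102 for the F test, and the platelet list at 3 days turned (adjusted p = 0.784), and the cause was not tested. Fits of only the 2 groups compared, with fewer arrays, gave 134, 61 and 3. Of these, 128, 40 and 1 were among the 401, 103 and 10 called genes. Of the genes called with the hepatocyte score, 203, 18 and 9 were. At an adjusted p under 0.10 there were 709, 444 and 659 (F test) and an overlap of 248. At an unadjusted p under 0.05 and 2-fold there were 63, 10 and 17 and an overlap of 7. With an estimated correlation 0, 0 and 0 lists passed, and with fry 12, 3 and 0, and the cause was not tested.

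The replicate block, which spends 2 degrees of freedom, gave 264, 0 and 0 genes, 118 for the F test and an overlap of 0. Over all genes the rats' numbers showed no sign of a pairing. The correlations of the 9 same-numbered pairs ran from -0.0950 to 0.0837, and the highest of the differently numbered pairs was 0.167. A pairing that touches few genes would not show in these correlations and is not excluded.

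With the T and natural killer cell score, which differs between the groups, 0, 0 and 0 genes passed, 6 by the F test, and 7 lists at 3 days, 0 at 10 days and 11 between the days (1 up and 10 down). The median SE of the called genes went from 0.104 to 0.205 at 3 days, from 0.0961 to 0.269 at 10 days and from 0.0955 to 0.132 between the days. These lists turned: at 3 days MHC class II (adjusted p = 0.483), B cell (0.742) and natural killer cell (0.237), at 10 days MHC class II (0.496), B cell (0.496), natural killer cell (0.496), T cell (0.993), phagocytic receptors (0.942), iron (0.942) and lysosome (0.891), and between the days T cell (0.713) and natural killer cell (0.633). RT1-DOa at 10 days went to -0.046. For the T and natural killer cell lists the construction of the score is the cause, and for the others the cause was not tested.

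Leaving out 1 array at a time, with fewer arrays, gave 190 to 327 genes at 3 days, 0 to 140 at 10 days, 0 to 18 between the days, 54 to 290 for the F test and an overlap of 0 to 79. The lists numbered 17 to 20, 8 to 15 and 8 to 16. The lowest 3-day count was without sham rat 2. The 10-day count was 0 without sham rat 2, sham rat 3 or 10-day rat 3.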

Other observations

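The test of peritoneal macrophage genes was chosen after the result was seen, and its limits were narrowed once its values were known.

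Of 19 general macrophage genes, 17 had a difference above 0 at 3 days and 4 passed limma's test, and at 10 days these were 15 and 0 (9 at an unadjusted p under 0.05). Aif1, a marker of macrophages, rose at 3 days (0.88, adjusted p = 0.0119) and differed by 0.69 at 10 days (adjusted p = 0.0595). Csf1r, the receptor for Csf1, differed by 0.49 and 0.59 (adjusted p = 0.143 and 0.104), and Mpeg1, a pore-forming protein of macrophages, by -0.25 and -0.10 (adjusted p = 0.240 and 0.648). The values of Csf1r and Mpeg1 did not pass limma's test. These genes were chosen after the changes had been seen.

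Prg4, F5 and Fn1, which rose at 3 days, are known from peritoneal macrophages. Such cells may be among the 3-day cells, and this was tested with 10 other genes known from them, whose median difference at 3 days was -0.017 (SD over genes 0.28). Serpinb2 was the 1 gene past the test (0.83, adjusted p = 0.0371), while Gata6, their transcription factor, differed by 0.03. Only 3 of the 10 genes lay neither near the filter nor high at baseline, so peritoneal cells and a change within the hepatic macrophages cannot be told apart.

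The first principal component took 31.3% of the variance and the second 18.7%. Sham arrays lay at -19.9, -10.5 and -9.38 on the first, 3-day arrays at 9.37, 13.9 and 9.42, and 10-day arrays at 4.70, 0.553 and 1.75. Among all probesets, 41 of the 191 that passed at 3 days carried no single gene symbol. Second probesets of Cd80, Mt2A and Spats2l had differences of the same sign as the ones used, at 3 and at 10 days. The second probeset of Rrm2, close to the filter, differed by -0.19 at 3 days where the one used differed by 0.46.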
